A study of Homo sapiens with 2 samples.

How the data were processed

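ATAC-seq (assay for transposase-accessible chromatin with sequencing) libraries were made from 2 human cell lines with a Tn5 transposase purified in the submitters' laboratory, from 50000 cells per reaction per the labels' protocols. The transposase cuts open chromatin and attaches sequencing adapters at the cut. One sample came from J76, which the labels describe as an acute T-lymphoblastic leukemia line. The other came from the human embryonic kidney line that the sample labels call T293 and the protocol calls 293T, written 293T here. There was 1 library per line, so no difference between the lines has a replicate check, and no p-value between the lines was computed.

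The data used were 1 peak list per library. Bowtie2 and MACS2 are named in the submitters' processing notes; their versions, the settings, and any removal of duplicates or shift of cut positions are not given in the sources used here. Each list was deposited by the authors in the narrowPeak layout. The fold column holds the authors' fold enrichment over background at the peak summit, a linear ratio. The next columns hold the authors' p-value and q-value as −log10 values. The integer score that the authors deposited equals 10 times the −log10 q, rounded down, in 100% of the J76 peaks and in nearly every 293T peak. Folds and −log10 values were used only to describe, rank or filter peaks within a list. The lists give no read counts, so the depth of both libraries is unknown and a missing peak is not evidence that a site was closed. The lowest −log10 q was 1.32 in J76 and 1.37 in 293T. Peaks within a list did not overlap one another, and no peak lay on the mitochondrial sequence.

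The genome build is not given in the sources used here. The names of the unplaced contigs in both lists belong to GRCh38, and positions are printed as GRCh38 on that ground, counted from 1. Genes came from a RefSeq table of GRCh38.p14 (19974 protein-coding genes on the autosomes and chromosome X). It holds no strand, transcript or sequence. The planned promoter readout was therefore replaced by a gene boundary readout, made after the table was seen: a gene had a boundary peak if a peak overlapped 1 kb either side of either of its ends, so a transcription start and a transcription end were not told apart. For shares of peaks the summit had to lie within 1 kb of a gene end. As a check of the build, all peaks were moved by 10 kb and counted again. The planned comparison of 20 transcription factor motifs needs the genome sequence and was not run, and random lists could not be matched on CpG content. Gene ontology terms were not used here. Chromosome Y and unplaced contigs were left out of the comparisons.

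A peak was shared if it overlapped a peak of the other line by at least 1 bp. Chance sharing was measured by placing the peaks of a line at random on their own chromosomes 100 times. Shares carry 95% Wilson intervals, which cover counting error only. Before the data were examined, 17 gene lists were fixed, and olfactory receptor genes were added by symbol as an 18th. All 338 list entries, 337 distinct genes, were found in the gene table. For each list, the number of members with a boundary peak in 293T only was subtracted from the number in J76 only. The difference was set against 10000 random lists of the same size, matched on 5 classes of gene length, as a description of these libraries. Gene length took the place of the planned matching on promoter CpG content and number of transcription starts. A list was said to lean to a line if it fell outside the central 95% of its random lists; 0.9 of 18 lists would do so by chance. A second readout counted distal peaks found in 1 line only (summit over 1 kb from any gene end) within 50 kb of a member's ends. It was planned at the same time for transcription starts, and gene ends were put in their place after the gene table was seen. A peak near several members counted once for each in the comparison with random lists, while the numbers of peaks given are of distinct peaks, except for the olfactory receptors. The genes named were set by rule: per list, up to 4 members with a boundary peak in 1 line only and up to 2 with one in both lines, highest fold first; per line, the 10 autosomal genes with the highest fold at a boundary peak found in that line only, leaving out provisional locus names; and per line the 3 such distal peaks with the highest fold. Some genes that this rule names are not reported here. Members named beyond these were chosen after their values were seen.

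Alternatives were a −log10 q of at least 5 or 10, the same number of peaks from each list (58730, or the 20000 highest by −log10 q), a reciprocal overlap of 50%, summits within 250 bp, windows of 500 bp or 2.5 kb, random lists without matching, and 500 kb in place of 1 Mb windows. Chosen after seeing the data were lists limited to the 12707 genes with no other gene end within 2 kb, lists limited to genes with a boundary peak in at least 1 line, random lists matched also on the ratio of 293T to J76 peaks in the 10 Mb window of each gene (5 classes), and, for the HOX genes, random runs of neighbouring genes. On simulated data, every one of the 200 genes given a peak was found among 19974 genes, 2.5% of 200 random lists fell outside the central 95%, and a planted list with 8 of 20 members in 1 line only stood at percentile 100. These runs check the code only. The peaks were put inside the window of genes without near neighbours. For the lists the states were shuffled over genes, so the 2.5% does not cover lists whose members are neighbours. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.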

Results

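Open chromatin was profiled in 2 unrelated human cell lines with the same purified transposase. J76 is a subline of the Jurkat T cell leukemia that lacks both chains of the T cell receptor, and 293T is an adherent line derived from embryonic kidney. Each line was represented by 1 library and 1 peak list. The J76 list held 59631 peaks and the 293T list 85597, of which 58730 and 84951 lay on the autosomes and chromosome X. Peaks had a median width of 370 bp (interquartile range 257 to 720) in J76 and 365 bp (254 to 693) in 293T, and covered 31.9 Mb and 46.5 Mb. The authors' fold enrichment had a median of 4.83 in J76 and 4.38 in 293T. Peaks with a −log10 q of at least 50 numbered 9178 in J76 and 9343 in 293T, whereas at a −log10 q of at least 5 they numbered 46460 and 61767, so the difference in list length lay among the weaker peaks.

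The first comparison asked how much of the accessible genome the lines had in common. Of the J76 peaks, 30696 overlapped a 293T peak (52.3%, 95% interval 51.9 to 52.7), and 30566 of the 293T peaks overlapped a J76 peak (36.0%, 35.7 to 36.3). Peaks placed at random gave 3.03% and 2.12% on average over 100 shuffles, and at most 3.17% and 2.24%. Sharing followed peak strength within each list. In the 10% of peaks with the highest −log10 q, 97.5% (97.0 to 97.9) of the J76 peaks and 90.9% (90.3 to 91.5) of the 293T peaks were shared, against 14.9% (14.0 to 15.9) and 6.60% (6.09 to 7.15) in the 10% with the lowest. Taking the same number of peaks from each list gave shares of 48.5% and 47.8%, which lists of equal length make nearly equal by construction, because about as many peaks of either list are shared.

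Shared peaks lay at gene ends more often than peaks found in one line only. In J76, 35.1% of shared peaks (34.6 to 35.7) but 4.84% of J76-only peaks (4.59 to 5.09) had their summit within 1 kb of the end of a protein-coding gene. In 293T the shares were 35.1% (34.6 to 35.6) and 5.50% (5.31 to 5.70). Such windows make up 2.39% of the chromosome span. Line-only peaks were mostly in gene bodies (40.4% in J76 and 45.9% in 293T) or between genes (54.8% and 48.6%). Over all peaks, 20.7% (20.4 to 21.0) in J76 and 16.2% (15.9 to 16.4) in 293T lay at a gene end, and moving every peak by 10 kb lowered this to 4.42% and 3.73%. With the same number of peaks from each list the order turned, to 20.7% in J76 and 21.6% in 293T. Among peaks with a −log10 q of at least 100, 84.6% (82.7 to 86.3) of 1480 in J76 and 82.5% (80.2 to 84.6) of 1140 in 293T were at a gene end.

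At the level of genes, 12115 of 19974 protein-coding genes (60.7%) had a boundary peak in both lines, and in 99.4% of these it was at the same end of the gene. A further 786 genes (3.94%) had one in J76 only, 1816 (9.09%) in 293T only and 5257 in neither. Genes of basic cell growth had peaks in both lines. All 20 cytosolic ribosomal protein genes had a boundary peak in both, among them RPL27 (fold 13.7 in J76 and 9.94 in 293T) and RPL11 (12.4 and 8.51). So did 19 of 20 DNA replication and cell cycle genes, led by CCNB1, the mitotic cyclin (12.3 and 14.5), and TOP2A, a DNA topoisomerase (12.4 and 11.6); the other member, ORC1, had none in either. These lists did not lean to either line (percentiles 62.5 and 70.5 of the random lists).

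The second comparison asked which lineage genes had a peak in only one of the lines. T cell genes leaned to J76. Of 20 genes of T cell receptor signalling, 14 had a boundary peak in J76 only, 5 in both lines and 0 in 293T only, and 0 of 10000 random lists had a difference as large. CD3E, a chain of the CD3 signalling complex, had a peak of fold 9.09 on chromosome 11 from 118315979 to 118317383 in J76 and none in 293T. The same held for PTPN22, a phosphatase that restrains receptor signalling (fold 9.54, chromosome 1, 113871561 to 113872619), and for THEMIS, which acts in thymocyte selection (fold 6.10). The kinase genes LCK (5.08) and ZAP70 (4.87) and the adaptor LAT (5.08) were also in J76 only, as were CD3G (4.90) and 7 other members. PRKCQ had boundary peaks in both (6.92 in J76 and 9.79 in 293T), as did PLCG1, which is used in many tissues (6.14 and 7.46). CD3D had a weak peak in both (3.75 and 3.55). PTPN22, ZAP70, LAT, CD3G, PLCG1 and CD3D have another gene end within 2 kb, so a peak there is not assigned to a single gene; among the 13 members without one, the difference was 10, at percentile 100.

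T cell surface molecules and leukocyte genes followed the same direction. Of 22 surface molecules, 8 had a boundary peak in J76 only and 0 in 293T only, with 5 in both and 9 in neither (0 of 10000 random lists as far). The adhesion molecule CD2 (8.29), the costimulatory receptor CD28 (7.99), CD6 (6.17) and CD1A (5.66) led the J76-only members, while CD8A had a peak in both (8.49 in J76 and 7.13 in 293T). Of 20 genes used across leukocytes, 9 were in J76 only, 1 in 293T only and 7 in both (0 of 10000). The J76-only members included ARHGAP15 (8.99), DOCK2, which drives leukocyte migration (8.87), TRAF3IP3 (8.39) and ARHGDIB (6.24). The member in 293T only was PTPN6 (5.07), and CD37 (3.65 and 11.3) and WAS (10.1 and 10.2) had peaks in both. PTPN6 and CD37 have other gene ends within 2 kb, and the 293T peak at CD37 is also a boundary peak of TEAD2.

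Among 22 transcription factors of the T lineage and of T cell leukemia, 12 had a boundary peak in both lines, 5 in J76 only, 1 in 293T only and 4 in neither (5 of 10000 random lists as far). The J76-only factors were IKZF3 (8.40), RUNX3 (6.28), LMO1 (4.86), RUNX1 (3.87) and TAL1, a leukemia oncogene (3.48). The receptor gene NOTCH3 (4.79) was in 293T only, and IKZF2 (5.91 in J76 and 7.95 in 293T) was in both. Erythroid and megakaryocyte genes also leaned to J76, but on 3 of 16 members, with 11 in neither line (130 of 10000 random lists as far). These were KLF1 (6.57), HBA1 (4.35) and EPOR (3.37), and GP9 and NFE2 had peaks in both (6.19 and 3.05 in J76, 7.03 and 5.13 in 293T). Without genes that have another gene end within 2 kb, this list stood at percentile 95.8 and no longer leaned. HBA1 has a near-identical copy, so its peak is uncertain.

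Kidney developmental regulators and HOX genes leaned to 293T, a call that did not hold among genes without a near neighbour. Of 18 kidney regulators, 6 had a boundary peak in 293T only, 1 in J76 only and 6 in both (95 of 10000 random lists as far). GDNF, a growth factor of ureteric bud outgrowth, had a peak of fold 9.88 on chromosome 5 from 37839799 to 37840905. It was followed by WT1 (6.67), LHX1 (5.12), SALL1 (4.00), HOXD11 (3.33) and EYA1 (2.92). HOXD11 is counted in both lists, so the leans of the kidney and HOX lists are not independent. The EYA1 peak was weak, with a −log10 q of 2.43. At a −log10 q of at least 5 the kidney list stood at percentile 2.135, just outside the central 95%. PAX2 was the member in J76 only (3.80). SIX2 had a peak in both (6.08 in J76 and 6.91 in 293T), and PAX8 in neither. Of 39 HOX genes, which set positional identity, 11 were in 293T only and 0 in J76 only, with 19 in both (1 of 10000 random lists as far). The 293T-only genes were led by HOXD1 (7.82), HOXA4 (4.78), HOXD11 (3.33) and HOXC11 (3.28), and 5 of the 11 lay in the HOXA cluster and 2 in each of the others. HOXC4 and HOXC6 share a peak found in both (11.7 in J76 and 6.06 in 293T). Neither list leaned once genes with another gene end within 2 kb were left out, although both differences kept their direction. J76-only minus 293T-only members then came to -3 over 15 kidney regulators (percentile 7.84), from -5 over 18, and to -4 over 19 HOX genes (percentile 2.60, just inside the central 95%), from -11 over 39. Against random runs of neighbouring genes, 20 of 10000 were as far as the HOX clusters.

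**Figure D1:**
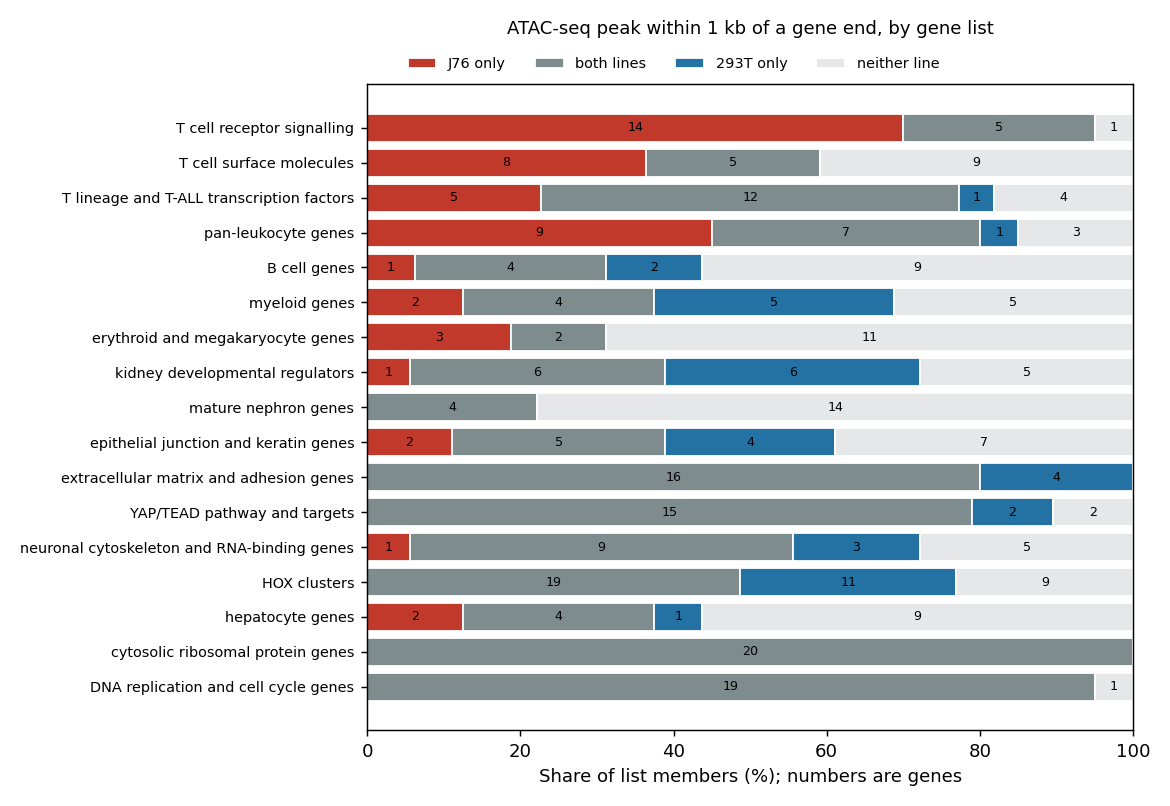
Share of the members of each of 17 gene lists (horizontal axis, percent) with an ATAC-seq peak within 1 kb of a gene end in J76 only (red), both lines (grey), 293T only (blue) or neither (light grey); the numbers count genes, from 1 library per line. T cell receptor signalling has 14 J76-only genes of 20, the HOX clusters have 11 293T-only genes of 39, and all 20 ribosomal protein genes are in both.

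The other lists lay within the central 95% of their random lists. Extracellular matrix and adhesion genes had 16 of 20 in both lines, 4 in 293T only and 0 in J76 only (percentile 8.28); CAV1, the main protein of caveolae, had a fold of 6.0, NID1 5.57, and COL4A1 and COL4A2 share a peak of 5.52. THBS1 and ITGAV were in both, with folds of 10.1 and 9.90 in J76 and 11.3 and 6.13 in 293T. For the YAP/TEAD pathway, which responds to cell adhesion, 15 of 19 were in both and 2 in 293T only (percentile 32.3). The latter were the targets NUAK2 (9.28) and CCN2 (8.05), while AMOT (9.44 in J76 and 6.15 in 293T) was in both. TEAD2 was in both, with its highest peaks at different ends of the gene, in J76 from 49363390 to 49363739 on chromosome 19 (4.51) and in 293T from 49338914 to 49340472 (11.3). A weaker J76 peak from 49340204 to 49340489 (3.65), the one given for CD37, overlaps that 293T peak, so both lines had a peak at that end. Epithelial genes had 4 of 18 in 293T only, among them TJP1 (8.13) and the neighbouring keratin genes KRT8 and KRT18 (6.25), and 2 in J76 only, including ESRP1 (7.35), at percentile 23.1; JUP (4.14 and 10.4) and OCLN (7.89 and 8.05) were in both. Neuronal genes had 3 of 18 in 293T only, GAP43 (8.05), DPYSL3 (6.87) and TUBB3 (4.10), and 1 in J76 only, INA (6.62), at percentile 32.0. MAP2 (11.4 and 8.63) and SNAP25 (10.3 and 7.75) were in both. Mature nephron genes had 14 of 18 in neither line and 4 in both, including PODXL (6.21 and 6.79), at percentile 72.1.

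Marker lists of cell types that neither label names did not lean to a line, apart from the erythroid genes. B cell genes had 9 of 16 in neither line, 1 in J76 only (BANK1, 5.05) and 2 in 293T only (VPREB3, 8.29, and FCRLA, 3.93), at percentile 43.2. EBF1 (8.39 in J76 and 8.10 in 293T) and CIITA (8.38 and 7.32) were in both. Myeloid genes had 2 of 16 in J76 only, among them CEBPE (5.45), and 5 in 293T only, among them S100A8 (5.01), ITGAM (3.96) and CSF1R (3.13), at percentile 5.04; CEBPA (9.50 and 6.49) and SPI1 (7.11 and 7.89) were in both. Hepatocyte genes had 9 of 16 in neither, 2 in J76 only and 1 in 293T only, all with folds under 4 (TTR 3.51, CYP2E1 2.69, FGG 3.96), at percentile 87.5, and TF (11.3 and 9.78) and TAT (10.3 and 10.6) were in both. Of 390 olfactory receptor genes, 352 had no boundary peak in either line, 8 had one in both, 13 in J76 only and 17 in 293T only (percentile 83.9). OR3A2 and OR1R1 share a J76-only peak (10.8), OR2B11 (8.47) was in 293T only, OR10P1 (7.10) in J76 only, and OR2L13 (12 and 13.4) and OR52K1 (6.38 and 10.7) in both. Receptor genes of this family are similar in sequence, so single members are uncertain. Among the genes named for the other lists, VPREB3, CIITA, S100A8, CSF1R, EPOR, SALL1, HOXD11, HOXC4, HOXC6, KRT8, KRT18, COL4A1, COL4A2, THBS1, TEAD2, TUBB3 and TF also have another gene end within 2 kb.

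Distal peaks leaned the same way as gene ends for the 4 T cell and leukocyte lists and the HOX genes, and to 293T for the YAP/TEAD genes, whose gene ends had not leaned. J76 had 26678 distal peaks not shared with 293T, and 293T had 51392 not shared with J76; a gene had on average 1.52 J76-only and 2.33 293T-only distal peaks within 50 kb of its ends. Around the T cell receptor signalling genes there were 75 distinct J76-only against 45 293T-only peaks, around the surface molecules 76 against 30, around the T lineage factors 120 against 83, and around the leukocyte genes 54 against 42. Counting a peak once for each member near it, 0 of 10000 random lists lay as far as each of the first 3 lists, and 133 as far as the leukocyte genes. IKZF1, which encodes a lymphoid transcription factor, had a boundary peak in both lines (3.81 in J76 and 6.61 in 293T) but 17 J76-only and 0 293T-only distal peaks. CD28 had 8 and 0, IL7R 9 and 0, and RUNX1 10 and 2, while BCL11B had 1 and 13, LMO1 1 and 6, and RUNX3 1 and 4. Members with more J76-only than 293T-only distal peaks numbered 15 against 3 with fewer among the signalling genes, 17 against 3 among the surface molecules, 16 against 6 among the T lineage factors and 9 against 8 among the leukocyte genes. Around the HOX genes there were 8 distinct J76-only and 44 293T-only peaks. Counted once for each member near it, as in the comparison, these came to 39 and 283. On that count 0 of 10000 random lists, and 0 of 10000 runs of neighbouring genes, were as far. The runs were matched on the number of genes but not on the length they span. Repeated counting of the same peaks in the compact HOX clusters therefore adds to this distance, by an amount that was not measured. The HOXC cluster and its 50 kb flanks held 27 293T-only peaks and 1 J76-only peak. Around the YAP/TEAD genes there were 32 against 103 (8 of 10000), with 19 293T-only and 0 J76-only peaks at PTPN14, 17 and 2 at YAP1, 11 and 0 at CRIM1, and 9 and 1 at CCN1. FRMD6 of the same list had 2 and 8, and 10 of the 19 members had more 293T-only peaks against 3 with more J76-only peaks. Some of these genes lie where 293T had more peaks over the whole region, with 448 293T against 136 J76 peaks in the 10 Mb window of PTPN14 (ratio 3.29, median of all windows 1.36). With random lists matched on this regional ratio as well, 7 of 10000 lay as far as the YAP/TEAD genes, and the 6 lists that leaned in distal peaks still leaned.

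The remaining 12 lists did not lean in distal peaks, but with matching on the regional ratio the ribosomal protein genes leaned to 293T (percentile 2.03) and the olfactory receptor genes to J76 (98.8). The kidney regulators, which leaned to 293T at gene ends, had 31 J76-only against 48 293T-only distal peaks (percentile 33.3), and the erythroid genes 20 against 17 (percentile 87.4). Ribosomal protein genes had 23 against 47 (percentile 4.22), extracellular matrix genes 26 against 71 (9.60), epithelial genes 22 against 50 (9.18) and myeloid genes 27 against 18 (96.8). Mature nephron genes had 31 against 43 (50.1), neuronal genes 22 against 38 (73.0), hepatocyte genes 12 against 18 (45.6), B cell genes 25 against 27 (84.9) and replication and cell cycle genes 36 against 34 (89.0). Olfactory receptor genes had 305 J76-only and 402 293T-only pairs of a gene and a distal peak (85.1).

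**Figure D2:**
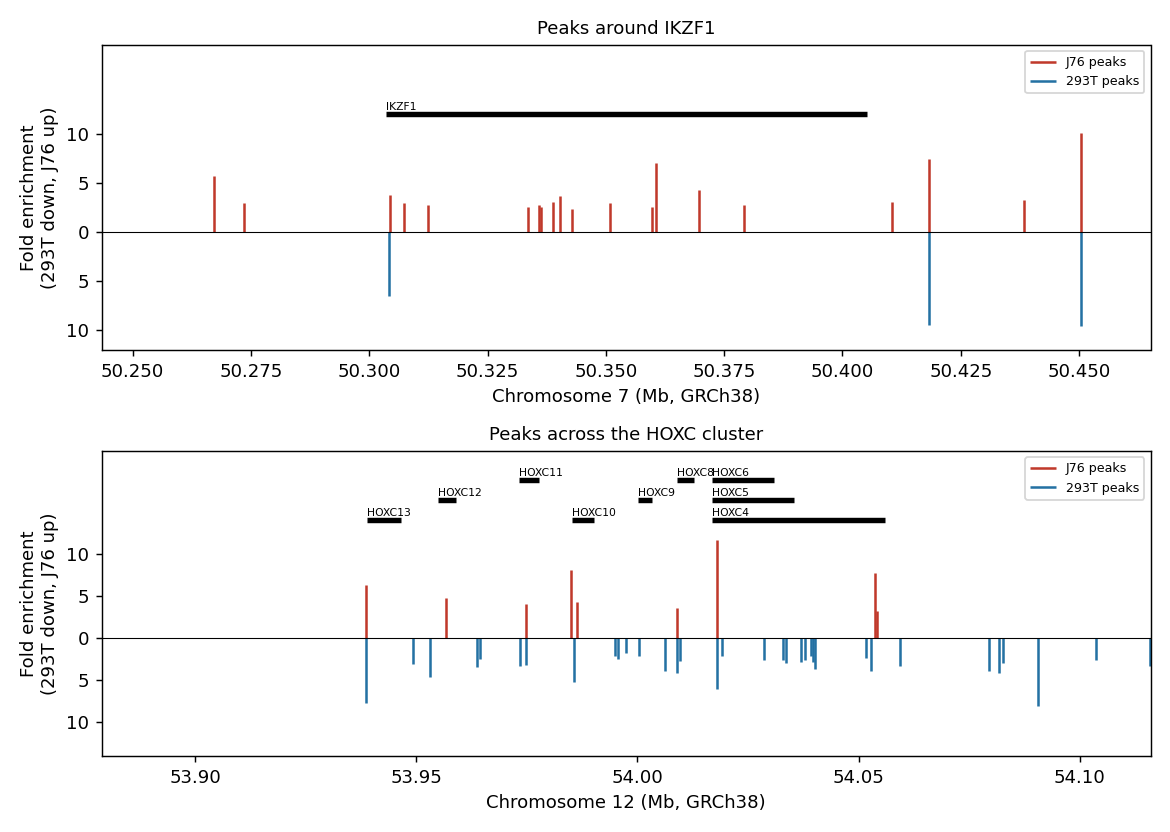
Peaks around IKZF1 on chromosome 7 and across the HOXC cluster on chromosome 12 (horizontal axis, Mb in GRCh38; vertical lines at peak summits, height the authors' fold enrichment, J76 upwards in red and 293T downwards in blue; black bars are genes). IKZF1 has 17 distal peaks in J76 only, and the HOXC cluster with 50 kb on either side has 27 peaks in 293T only.

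The strongest boundary peaks found in only one line were at genes of many functions, with several zinc finger genes among them. In J76 they were at ZNF737 (fold 12.4), ZNF43 (12.2), PSMA8, a testis proteasome subunit (11.8), MCCC1 of leucine breakdown (11.8), SIX6 (11.2), AKR1E2 (11.1), GSTM1, a glutathione transferase (11.1), ZNF491 (11), TSPYL5 (10.9) and FAM111B (10.8). In 293T they were at ZNF470 and its divergent neighbour ZNF470-DT (one shared peak, 14.9), ZNF493 (14.1), FMN1 (14.1), ZNF582 (14.0), MAP3K13 (13.9), TTC12 (13.8), IFTAP (13.8), ZNF841 (13.8) and MTERF2 (13.6). GSTM1 has close paralogs and is uncertain, and MAP3K13 has another gene end within 2 kb. The strongest distal J76-only peaks lay on chromosome 18 from 77899902 to 77900612 (fold 14.7, 622 kb from GALR1), on chromosome 19 from 20999633 to 21000367 (13.7, 20.8 kb from ZNF430) and on chromosome 3 from 7876716 to 7877763 (13.7, 135 kb from GRM7). Those of 293T lay on chromosome 9 from 42725289 to 42725980 (19.2, 169 kb from LOC112268044), on chromosome 14 from 82642408 to 82642979 (17.8, 1109 kb from SEL1L) and on chromosome 7 from 52159291 to 52160058 (17.6, 843 kb from COBL). None of the 6 lay inside a protein-coding gene. Peaks in repeated or poorly mapped sequence were not filtered out here, so single peaks of high fold such as these are uncertain.

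The ratio of 293T to J76 peaks differed between autosomes, and chromosome 13 had the highest. Chromosome 13 held 1236 J76 peaks and 3223 293T peaks, a ratio of 2.61, and chromosome 6 held 3481 and 6203 (1.78). Chromosome 19 held 2558 and 2326 (0.91), chromosome 20 1729 and 1523 (0.88) and chromosome 22 1193 and 1060 (0.89). With the same number of peaks from each list the ratio was 1.47 on chromosome 13, 1.15 on chromosome 6, between 0.89 and 0.99 on chromosomes 8 to 12, and between 0.68 and 0.77 on chromosomes 14, 19, 20, 21 and 22. Of 2783 windows of 1 Mb with a peak in either line, 2763 had one in both. Among the 2474 windows with at least 20 peaks in all, 243 had at least 4 times as many peaks in 293T and 12 at least 4 times as many in J76. There were 0 runs of 3 windows with peaks in one line and none in the other. With 500 kb windows there were 4, all without J76 peaks; the one with the most 293T peaks (38) was on chromosome 9 from 21500001 to 23000000 and spans MTAP, CDKN2A, CDKN2B and DMRTA1. Read depth along the chromosomes was not used here, so differences in DNA copy number between the lines were not corrected. Peaks in repeated or poorly mapped sequence were kept in these counts.

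**Figure D3:**
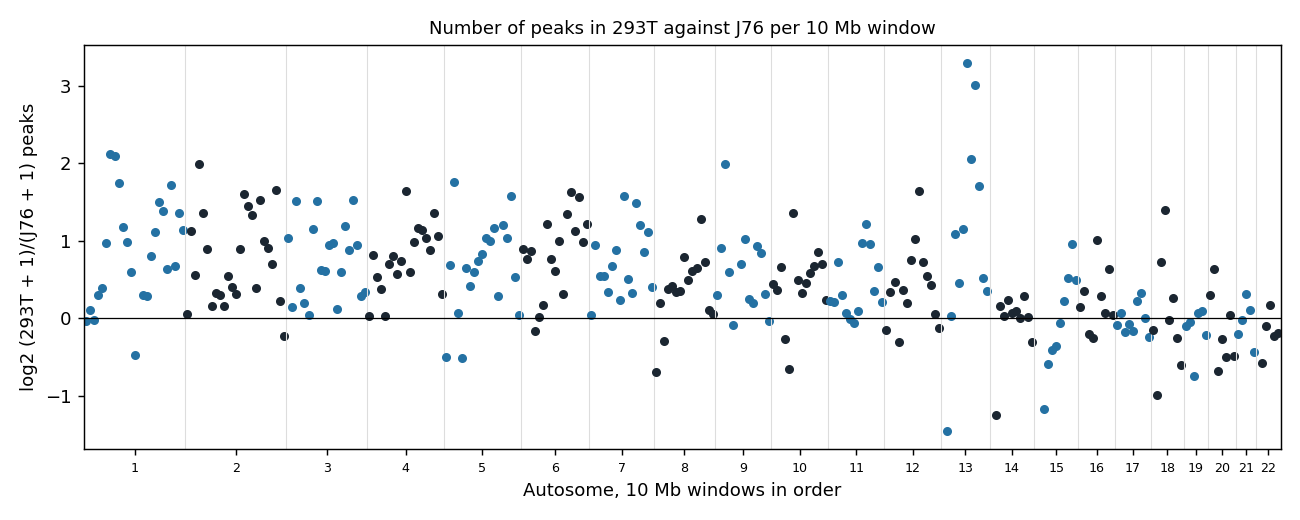
Log2 ratio of the number of peaks, (293T + 1)/(J76 + 1), in 289 windows of 10 Mb with at least 60 peaks in all (1 point per window, autosomes in order, 1 library per line). The ratio without the added 1 is above 1 in 236 windows and runs from 0.359 to 9.92, both on chromosome 13. With the same number of peaks from each list, which is not drawn, it is above 1 in 142 windows and runs from 0.240 on chromosome 14 to 4.33 on chromosome 13. The lowest values are of the windows from 10 to 20 Mb on these chromosomes, at their centromeres, and peaks in repeated sequence were not filtered out.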

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

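Sequence that no comparison used also held peaks. The J76 list had 674 peaks on unplaced contigs and the 293T list 528, with no control sample to set them against.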

How the results depend on the processing

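No paired analysis was possible because each line had 1 library, and no replicate could be left out. The settings limited to genes without a near neighbour, or with a boundary peak in at least 1 line, and the matching on the regional ratio of peaks were chosen after seeing the data. At a −log10 q of at least 10 the lists fell to 30806 peaks in J76 and 38882 in 293T, and the median width rose to 664 bp and 706 bp. The shared share of J76 and of 293T peaks was 41.8% and 28.9% with a reciprocal overlap of 50%, 47.3% and 32.7% with summits within 250 bp, 58.5% and 43.9% at a −log10 q of at least 5, 48.5% and 47.8% with the same number of peaks from each list, and 65.3% and 65.2% with 20000 peaks from each. The share of peaks at a gene end in J76 and 293T was 17.5% and 13.2% within 500 bp, 25.9% and 20.7% within 2.5 kb, and 24.7% and 20.8% at a −log10 q of at least 5; with equal numbers it was 21.6% in 293T, above J76. Genes with a boundary peak in both lines numbered 6565 among genes with no other gene end within 2 kb, where fewer genes are counted, and 0 lists then leaned to 293T in place of 2. The number of lists leaning to J76 stayed between 4 and 6, and olfactory receptors joined it only without matching. In distal peaks, matching on the regional ratio raised the lists leaning to J76 from 4 to 5 and to 293T from 2 to 3. Runs of windows with peaks in one line numbered 4 with 500 kb in place of 1 Mb windows. The cause of the shifts above was not tested, apart from the smaller number of peaks or genes that a setting itself leaves. The other 30 values that answer a comparison stayed within their interval or within 1.5 times, counts of genes with a peak in one line only among them (583 to 935 for J76 and 1392 to 1860 for 293T). Alternatives of the motif comparison were not run. The unknown depth limits each statement that a peak was absent.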

Other observations

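The windows, regions and gene counts below were singled out after the data were seen. Tests chosen only after the result was seen were the zinc finger genes against random lists and the chromosome 9 genes without a J76 peak. In J76 the highest numbers of distal line-only peaks within 50 kb of a gene, after IKZF1, were at MBNL1, an RNA splicing regulator (14 J76-only and 9 293T-only), MGAT4A, a glycosyltransferase (12 and 0), ARHGEF10 (11 and 0) and MYT1 (11 and 0); CDK6, a cell cycle kinase, had 10 and 5. In 293T they were at SEMA3C, a secreted guidance protein (22 293T-only and 0 J76-only), ROR1, a receptor of Wnt signalling (21 and 0), EDARADD (20 and 1), HOXC4 (20 and 0), RBM20 (19 and 3), TFPI (19 and 1), GULP1 (19 and 2) and PTPN14 (19 and 0). Most of these 293T genes lay in 10 Mb windows where 293T had more peaks as a whole, with ratios of 293T to J76 peaks of 2.99 for SEMA3C, 4.37 for ROR1, 2.58 for EDARADD, 2.90 for GULP1 and TFPI, 3.29 for PTPN14 and 1.81 for RBM20, against 1.15 for HOXC4 and a median of 1.36 over all windows. Of the J76 genes, ARHGEF10 (0.617) and MYT1 (0.712) lay in windows with more J76 peaks as a whole. The ratio was 1.11 for MGAT4A, 1.42 for CDK6, 1.60 for IKZF1 and 1.84 for MBNL1.

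Of the 12 windows of 1 Mb with at least 4 times as many peaks in J76, all but that on chromosome 8 lay at or close to a centromere. Several were on acrocentric chromosomes: 39 J76 and 2 293T peaks from 16 Mb on chromosome 13, 34 and 7 from 17 Mb on chromosome 14, 31 and 4 from 11 Mb on chromosome 21, and 27 and 3 from 13 Mb on chromosome 22. On chromosome 20 the windows from 26 Mb and 27 Mb held 59 and 61 J76 peaks against 12 and 9. On chromosome 15, which is also acrocentric, there were 34 and 7 from 20 Mb and 27 and 2 from 21 Mb, and on chromosome 22 also 47 and 11 from 14 Mb. The rest were 20 and 4 from 15 Mb on chromosome 18, 22 and 5 from 24 Mb on chromosome 19, and 24 and 6 from 59 Mb on chromosome 8. Peaks in repeated or poorly mapped sequence were not filtered out here, and the effect of such sequence on these windows was not tested.

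On chromosome 9, J76 had 0 peaks between 21119766 and 23492202, a stretch of 2.37 Mb, while 293T had 38 peaks from 21500001 to 23000000 and a boundary peak at each of the 4 genes there: MTAP, CDKN2A, CDKN2B and DMRTA1, of which CDKN2A and CDKN2B encode inhibitors of cell cycle kinases. Of 3364 other overlapping spans of the same length with as many 293T peaks, 0% lacked J76 peaks, but the span was chosen as the one without J76 peaks that held the most 293T peaks, so this share was fixed by the choice and does not exclude J76 peaks that are sparse by chance. Loss of DNA copies in J76 is a candidate explanation that needs 0 of the 4 genes to have a J76 peak, and 0 did, which the choice of a stretch without J76 peaks fixed as well. Chance, loss of DNA and closed chromatin cannot be told apart here, since read depth was not used.

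On chromosome 13 from 60 to 90 Mb, which touches 38 protein-coding genes, 293T had 1626 peaks and J76 245, a ratio of 6.64, against 1.61 over the rest of the chromosome. In 293T, 91.6% of these peaks were not shared, 1.66% lay within 1 kb of a gene end, and their median fold was 3.50. The longer 293T list does not account for all of it, since with the same number of peaks from each list the ratio was 2.96. More DNA copies in 293T may contribute but cannot be told apart from a change in chromatin. The 140 J76 peaks of the span that were shared ranked higher in 293T by a median of 2.73 percentile points (bootstrap 95% interval 1.09 to 7.39, median of other spans -0.61). This was above only 87.6% of 105 other spans of 30 Mb. Each J76 peak was paired with the strongest 293T peak that overlapped it. The bootstrap drew neighbouring peaks of 1 library per line as independent, so its interval does not cover variation between libraries or regions. A difference in chromatin between the lines stays open as untested. The span was not alone in its direction. On chromosome 1 the windows from 60 to 70 and 70 to 80 Mb had ratios of 4.37 and 4.31, against a median of 1.36 over all 10 Mb windows. The window from 90 to 100 Mb on chromosome 13, counted with the rest of the chromosome, had a ratio of 3.27.

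Zinc finger genes with a ZNF symbol had peaks of fold 10 or more in one line and none in the other more often than other genes, but peaks of any fold in one line only were not more frequent (16.5% of those with a boundary peak, against 17.7% of all genes with one in at least 1 line). Of 477 such genes, 23 had a boundary peak of fold 10 or more in one line only (6 in J76 and 17 in 293T), against a mean of 3.58 in random lists matched on gene length, and 0 of 10000 random lists had as many. The random lists drew genes from any place, while 240 of the 477 lay on chromosome 19. Neighbouring genes that vary together were therefore not allowed for, and the 0 of 10000 may overstate the excess. An effect of chromosome 19 on all its genes alike was argued against as the whole cause. Such a peak was at 16 of 240 zinc finger genes there (6.67%, 95% interval 4.14 to 10.6) but at 0.330% of 1211 other genes (0.129 to 0.846). The other genes came from the whole chromosome and include ZNF470-DT, which shares the peak of ZNF470. The intervals count neighbouring genes as independent. Off chromosome 19 it was 7 of 237 zinc finger genes (2.95%, 1.44 to 5.97). An effect of smaller parts of the chromosome that hold many zinc finger genes, or on zinc finger genes alone, therefore stays open. High fold at zinc finger genes in general was argued against as the whole cause too: among genes with a peak of fold 10 or more in either line, 10.8% of 213 zinc finger genes (7.30 to 15.7) and 2.99% of 4151 others (2.51 to 3.55) were line-only. Such a peak was found at 213 of 477 zinc finger genes and at 4151 of 19497 other genes, so high fold can supply a part of the excess. A candidate explanation is that single zinc finger genes are switched on or off as units in each line, which these lists did not test, and deletion of single genes or reads shared between similar copies was not tested.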
